A study of Mus musculus with 5 samples.

How the data were processed

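DNase-seq maps open chromatin by where DNase I cleaves the DNA of intact nuclei. It was run on liver from mouse embryos at day 13.5, a stage when the organ is the main site of red cell production. Per the labels the 5 libraries are biological replicates 1 to 5 of 1 group, from a strain given as C57BL/6N,129 with an LCR deletion, a homozygous globin mutation and a multiple-copy YAC (yeast artificial chromosome). The labels do not say which locus control region (LCR) was deleted or what the YAC carries, and give the sex as not collected. All files were made on mm10, and no deposited interval ran past the end of a reference chromosome.

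The authors called peaks in each library separately and deposited 2 peak lists per library, a longer and a shorter one. The signal in both lists is a peak density that the authors scaled to library depth. Its low values were whole multiples of 1 step per library, to within 0.1 of a step, as a density scaled to a fixed number of tags would give. Read as a density per Mtag (mega-tag), the inverse of the step implied 89.0, 146, 75.5, 125 and 151 Mtags in replicates 1 to 5, and no other statement of depth was used. Because it is a smoothed density, no count test was applied to it. The deposited peak lists hold no p-value or q-value. A separate deposited file gives, per run of bases, the false discovery rate (FDR, the p-value unit of these files) of the DNase cleavage rate, listed by the authors only below 0.05. Every peak of the longer list met a run at an FDR of 0.05 or less, and every peak of the shorter list met one at 0.001 or less. Footprints, short protected stretches inside open chromatin, were deposited at an FDR of 0.01. The aligner, the peak caller and the footprint caller are not given in the sources used here. The longer list was used throughout, and the density is the authors' own value. The column that could hold a summit was 75 in every peak, so the peak centre was used.

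Peaks of the 5 libraries that overlapped by 1 bp or more were merged into regions, and a region counted as found in a library when a peak of that library lay in it. Overlap of a pair was the Jaccard index in bp, beside the same peaks placed at random on their chromosomes with bedtools 2.31.1. Agreement of density was Spearman's rho across regions, with 0 where a library had no peak; regions are not replicates, so no p was computed. A promoter was the sequence within 500 bp of a transcription start site (TSS) of GENCODE vM21, and a distal region lay farther than 500 bp from any TSS. Open in all libraries means that a region found in all 5 libraries lay at the promoter. Counts of libraries for a single gene use each library's own peaks there, which gave a different answer for 82 of 21827 protein-coding genes, among the list genes only Spi1.

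The 15 gene lists, 19 motifs, windows, tests and the rule for naming genes were fixed before the data were examined. The rule names all globin genes. For each list it names the 2 genes with the highest mean rank of promoter density, the gene with most distal regions and up to 2 genes, in alphabetical order, without a promoter peak. It also names the 10 genes with most distal regions, the 10 strongest regions found in all libraries and the 2 strongest regions called in each library alone. Some items that the rule selects are not reported here. Any other gene named was chosen after its values were seen. Ahsp was not found in the annotation by its symbol. Alas2 stands in both the erythroid and the haem list.

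Promoters of each list were compared with all other protein-coding genes by a two-sided Fisher's exact test, and distal regions within 50 kb of a gene's TSSs with 100000 random lists of the same size by a two-sided permutation test, whose smallest p is 2.0e-05. Both were adjusted by Benjamini-Hochberg over the 15 lists. A region at any TSS of a gene's protein-coding transcripts counted for that gene, so genes with more TSSs have more chances. Neither test allowed for the number of TSSs per gene. Genes are the units of these tests, which therefore say nothing about spread between libraries; that spread is given as an SD. Globin windows were counted in peaks and in bp listed at an FDR below 0.05 per kb, and ranked among all windows of the same size on their chromosome. Annotated globin sites came from the RefSeq functional elements of the same build. Motif matches within 75 bp of the peak centre were set against flanks 500 to 650 bp away, with 0.5 added to both counts, and matches inside peaks that met a footprint against random positions in the same peaks. Each log2 ratio was tested over the 5 libraries with a two-sided exact sign-flip permutation test. Its smallest possible p with 5 libraries is 0.0625, so no motif or location result can pass 0.05, and 0.0848 is the smallest value after adjustment over the 38 motif tests or the 19 footprint tests. Uniqueness was the share of 32-base words that occur more than once in the reference.

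Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, with random seed 1. The code was tested on simulated data. Lists of 24 genes simulated as mostly open were recovered in 100% of 100 runs and lists of 24 genes with 2 added distal regions per gene in 100% of 20 runs, while 0.357% of unchanged lists were called in either test. A planted motif ratio came back with a log2 difference of 0.05, and merging was checked against bedtools with a difference of 0 regions. In the same 5000 simulated windows, 4 motifs that were not planted had log2 ratios of up to 0.356 in size.

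The alternatives tried were the shorter peak list, an equal number of top-scored peaks, overlap of 50% of both peaks, regions in 3 or more libraries, promoters of 1000 bp, a distal window of 100 kb, random lists matched on nearby TSSs, an LCR window of 20 kb, motif windows of 50 bp, base-shuffled background, footprints in peaks found in all libraries, and leaving out each replicate. Leaving out peaks with 50% or more of their bases soft-masked (marked as repeats) in the reference was added after seeing the data. With 1 group, no difference between conditions could be tested. Reads and alignments were not used here, and no genome other than the mouse reference was used.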

Results

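Open chromatin was mapped by DNase-seq in 5 libraries of mouse fetal liver at embryonic day 13.5, all of 1 group, biological replicates 1 to 5. The strain label names an LCR deletion, a homozygous globin mutation and a multiple-copy YAC, and no second group was available for comparison. The comparisons the design allows are between replicates, between gene groups within the tissue, and between the globin loci and the rest of their chromosomes. The libraries held 59490, 51199, 33541, 57877 and 68072 peaks in replicates 1 to 5, a mean of 54036 ± 12938 (SD, n = 5), covering 10.1, 10.4, 6.97, 12.6 and 13.4 Mb. Median peak density was 0.640, 0.664, 1.26, 0.921 and 0.721. The depth implied by the density steps was 89.0, 146, 75.5, 125 and 151 Mtags (mega-tags), if the density is per Mtag.

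The first question was which open regions the replicates share. The strongest regions found in all 5 libraries included the promoters of Dynlt1b, a dynein light chain gene (chromosome 17, 6429981 to 6430240, density 37.0 ± 9.99, SD, n = 5), of Sde2 (chromosome 1, 180850801 to 180851140, 23.2 ± 5.24), of Eif5a, a translation factor gene (chromosome 11, 69921281 to 69921720, 20.5 ± 6.96), and a region 350 bp from the TSS of Tle4, a corepressor gene (chromosome 19, 14598241 to 14598560, 19.4 ± 4.50). The 10 regions were picked by their lowest within-library rank, and among them the highest mean density, 92.9 ± 38.4, lay on an annotated ribosomal RNA gene on chromosome 17 (39846781 to 39846920), where 82.6% of 32-base words occur more than once in the genome. In another 5 of the 10 strongest regions 61.4% or more of the words were repeated. They lay in an exon of Lars2 (chromosome 9, 123461881, 61.4% repeated), at a microRNA gene in Zc3h7a (chromosome 16, 11144171, 95.8%), between genes 21564 bp from the TSS of Igf2bp3 (chromosome 6, 49236421, 77.5%) and 109640 bp from that of Gm8797 (chromosome 3, 5860361, 100%), and in an intron of Il31ra (chromosome 13, 112578161, 75.2%). For Dynlt1b the share was 50.2%, and for Sde2, Tle4 and Eif5a it was 0%.

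Merging gave 109324 regions, of which 22404 (20.5%) were found in all 5 libraries and 55434 in only 1, with 12581, 10334 and 8571 in 2, 3 and 4 libraries. The 10 pairs of libraries had a mean Jaccard index of 0.401 ± 0.071 (SD), from 0.320 for replicates 1 and 4 to 0.503 for replicates 4 and 5, against 0.00212 for peaks placed at random. On average 63.7% ± 8.30 of the peaks of a pair overlapped. Across all regions, which are not replicates, Spearman's rho of density averaged 0.619 (0.448 to 0.754), and across regions found in all libraries 0.897 (0.800 to 0.961). The regions found in all remaining libraries numbered 27605 without replicate 3, 24689 without replicate 1 and 22482 to 23386 without 1 of the others. The mean Jaccard index was 0.437 without replicate 1 and 0.418 without replicate 3.

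Replicate 1 stood apart in the regions it alone had. There were 23927 of these, 41.7% of its regions, against 5634 (11.6%), 2818 (8.85%), 9200 (16.6%) and 13855 (21.4%) in replicates 2 to 5. A GA repeat lay near the centre of 44.2% of them, against at most 0.144% of the regions called only in another library, and 82.9% were mostly soft-masked as repeats in the reference, against 13.8% to 20.9% elsewhere. Regions missing from 1 library only numbered 2253, 262, 5143, 827 and 86. The strongest region called only in replicate 1 lay in the promoter of the long noncoding RNA gene Gm28548 (chromosome 9, 104362061 to 104362240, density 24.5, 100% repeated words), followed by an intron of Serinc3 (chromosome 2, 163642821 to 163643100, density 7.08). In the other libraries the strongest such regions were mostly promoters: Kif9 (1.83) and Gorab (1.67) in replicate 2, Ddx39b (5.31) and Casp9 (2.94) in replicate 3, and Pop7 (4.86) in replicate 5. Replicate 4 had a region 524 bp from the TSS of Rmnd5a (5.28), and replicate 5 also had one 4291 bp from that of Sertad1 (4.99).

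**Figure D1:**
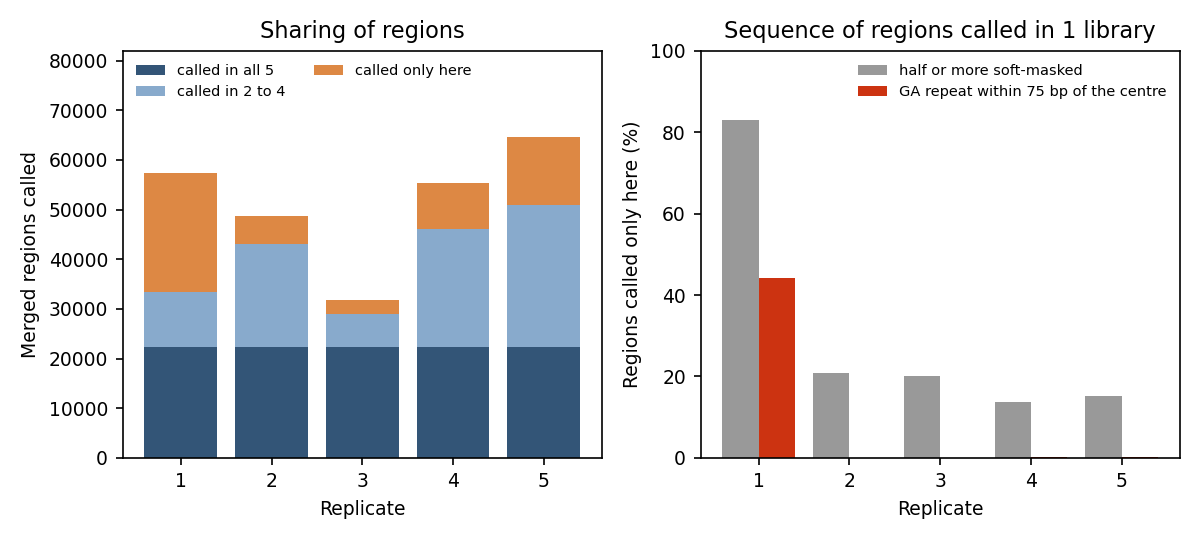
Left, stacked bars of the number of merged regions per replicate, split into those called in all 5 libraries (22404), in 2 to 4, or only there (23927 in replicate 1); right, the percentage of the regions called in 1 library that are mostly soft-masked (grey) or hold a GA repeat within 75 bp of the centre (red). Only replicate 1 shows a red bar of visible height, at 44.2%.

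The regions found in all libraries lay mainly at promoters. Of them 56.0% were within 500 bp of a TSS, against 3.01% of the same regions placed at random; 3.52% lay in exons, 23.4% in introns (random 43.5%) and 17% between genes (random 50.1%). Per library the promoter share was 36.7% ± 5.95 (SD, n = 5) against 2.78%, a log2 ratio of 3.71 ± 0.23 with the same sign in all 5 libraries (exact sign-flip permutation p = 0.063, the smallest possible). This left 12554 promoter and 9850 distal regions, and 10403 of 21827 protein-coding genes (47.7%) had a promoter open in all libraries. The share at promoters was 66.2% with the shorter peak list and 41.8% for regions in 3 or more libraries.

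Genes of the erythroid list were open almost without exception. Of the 24 erythroid genes, 23 had a promoter open in all 5 libraries, against 47.6% of other genes (Fisher's exact test across genes, two-sided, adjusted p = 1.03e-05). The share per library was 98.3% ± 2.28 (SD, n = 5). Over all protein-coding genes the share per library was 49.2% to 60.4%, the value to set beside the per-library shares of each list. Epb41, which encodes protein 4.1 of the red cell membrane skeleton (ENSMUSG00000028906.16, chromosome 4, 131923413 to 132075321), had a promoter density of 19.7 ± 4.53 and a mean rank in the 99.9th percentile of peaks. Zfpm1, which encodes the GATA1 partner FOG1 (ENSMUSG00000049577.15, chromosome 8, 122282141 to 122337251), had 13.8 ± 2.40. The exception was Alas2, the erythroid enzyme of the first step of haem synthesis (chromosome X, 150547375 to 150570638), with a promoter peak in 3 of 5 libraries.

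Of the 11 haem synthesis genes, 9 were open in all libraries (adjusted p = 0.0433, Fisher's exact test across genes; 87.3% ± 4.98 per library). The strongest were Slc25a38, a mitochondrial glycine carrier gene (chromosome 9, 10.8 ± 4.32), and Fech, the gene of ferrochelatase, which inserts iron (chromosome 18, 9.96 ± 3.95). The exceptions were Alas2 and Slc25a37, the mitochondrial iron carrier gene (mitoferrin 1, chromosome 14, 69241848 to 69285112), without a peak in any library. All 32-base words of the Slc25a37 promoter occur more than once in the reference, and no library had a region between 69253900 and 69391294, a stretch of 137 kb. By the same exact test, the call for haem genes was lost with promoters of 1000 bp (adjusted p = 0.0504) and without replicate 3 (0.0761).

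All 14 housekeeping promoters (adjusted p = 0.000233) and all 12 cell cycle promoters (0.000488) were open in every library, by Fisher's exact test across genes. Among them were Rplp0, a ribosomal protein gene (13.5 ± 2.51), Sdha, a mitochondrial enzyme gene (11.1 ± 3.18), and the cyclin genes Ccne1 (14.7 ± 5.21) and Ccna2 (11.7 ± 2.48).

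Liver cell genes were mostly without a shared promoter region. Of 22 hepatoblast genes only Cebpa, a liver and myeloid transcription factor gene (chromosome 7, 1.84 ± 0.630), and Trf, the transferrin gene (0.743 ± 0.216), were open in all libraries (adjusted p = 0.000488, Fisher's exact test across genes, lower than other genes), and 9 had no promoter peak in any library. Per library the share was 27.3% ± 9.64. Foxa3 had a peak in 4 of 5 libraries, and Krt8, Afp (alpha-fetoprotein) and Ahsg had none. None of the 13 adult hepatocyte genes, among them Cps1 and Cyp1a2, had a promoter peak in any library (adjusted p = 0.000714, Fisher's exact test across genes).

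Macrophage, endothelial, stellate, lymphoid and muscle genes were also open less often than other genes. None of 14 macrophage and myeloid genes (adjusted p = 0.000488, Fisher's exact test across genes) and none of 10 endothelial genes (0.00459) was open in all libraries. Cd68 had a peak in 4 and Vcam1 in 3 of 5 libraries, and Adgre1, C1qa and Fcgr1 had none. Of the endothelial genes Kdr had a peak in 3 and Tie1 in 1, and Cdh5, Emcn and Flt4 had none. One gene each of 10 was open in the stellate (Lhx2, 1.07 ± 0.338), lymphoid (Ebf1, 1.82 ± 0.375) and muscle lists (Mylpf, 5.49 ± 1.80), each at an adjusted p of 0.0342. Col1a2 had a peak in 4, Col1a1 in 2, Ttn in 3 and Il7r in 1 of 5 libraries, and Acta2, Dcn, Cd3d, Cd79a, Actc1 and Ckm had none. These last 3 calls were lost under at least 1 alternative: stellate with regions in 3 or more libraries, promoters of 1000 bp or replicate 3 left out, lymphoid with the shorter peak list, and muscle with the shorter list or regions in 3 or more libraries. Per library the shares were 12.9% ± 5.98 for macrophage, 12.0% ± 8.37 for endothelial, 34.0% ± 20.7 for stellate, 12.0% ± 4.47 for lymphoid and 16% ± 5.48 for muscle genes.

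For the other 4 lists no difference from other genes was detected. Of 13 stem and progenitor genes, 7 were open in all libraries (adjusted p = 0.784, Fisher's exact test across genes), led by Lyl1 (9.67 ± 2.23) and Runx1 (4.78 ± 1.51), while Erg and Hoxa9 had no promoter peak. Of 10 globin genes 4 were open (0.784). Of 10 megakaryocyte genes 2 were open (0.131), Gp1ba (1.13 ± 0.142) and Itga2b (0.919 ± 0.173), and Gp9 had no promoter peak. Of 10 neuronal genes 2 were open (0.131), Tubb3 (1.07 ± 0.453) and Syn1 (0.658 ± 0.148), Slc17a7 had a peak in 3 libraries, and Gad1 and Neurod2 had none. Per library the shares were 66.2% ± 6.88 for stem, 44.0% ± 5.48 for globin, 32% ± 13.0 for megakaryocyte and 34.0% ± 16.7 for neuronal genes. The matching shares over all protein-coding genes were 49.2% to 60.4%. Megakaryocyte genes were lower with the shorter peak list (adjusted p = 0.0112) and neuronal genes with an equal number of top-scored peaks (0.0354), by the same exact test across genes.

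**Figure D2:**
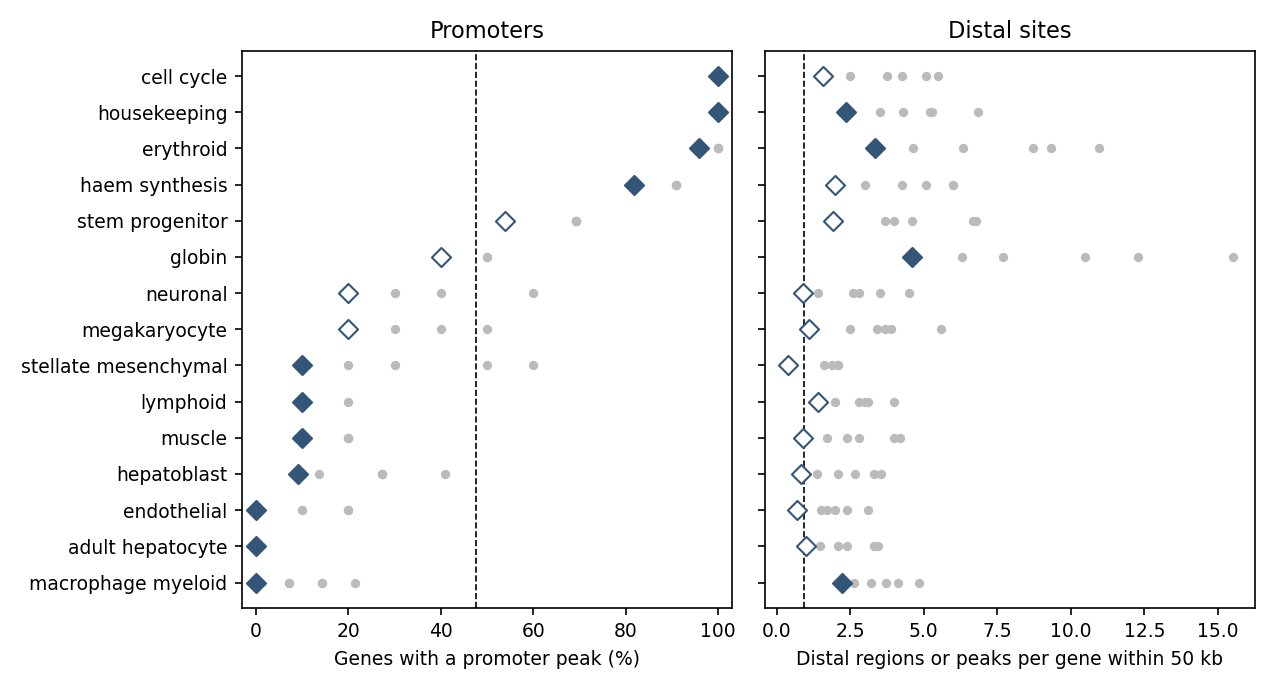
For each gene list, the percentage of genes with a promoter open in all 5 libraries (left) and the mean number of distal regions found in all libraries within 50 kb (right), as diamonds, filled where the adjusted p is below 0.05 (for globin distal regions that p does not allow for regions counted at several neighbouring genes); grey points are the values in each library from its own peaks and dashed lines the value over all protein-coding genes (47.7% and 0.940). Erythroid genes lie at 95.8% and 3.33, adult hepatocyte genes at 0% and 1.0. The dashed lines apply to the diamonds. For the grey points the values over all genes were 49.2% to 60.4% and 1.51 to 3.74.

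Distal regions gathered around erythroid genes. Random lists had about 0.940 distal regions per gene within 50 kb. Erythroid genes had 3.33 (3.55-fold), at the smallest p that 100000 random lists allow (2.0e-05, permutation test across genes, adjusted p = 0.000150). Zfpm1 had 10 such regions. The globin list had 4.6 per gene, but all 46 counts came from the 5 neighbouring alpha-globin genes, with 8 to 10 each and most regions counted for several genes, while the 5 beta-globin genes had 0. Random lists of scattered genes do not allow for this shared counting, so no p is given for the globin list. Housekeeping genes had 2.36 (adjusted p = 0.0361), with 8 at Actb, and macrophage and myeloid genes 2.21 (0.0478), with 8 at Fcgr1, by the same permutation test. Both of these calls were lost with the shorter peak list (adjusted p 0.0600 and 0.197) and with a window of 100 kb (0.0510 and 0.0643). The macrophage and myeloid call was also lost by the same permutation test with regions in 3 or more libraries (0.279) and without replicate 1 (0.0653), 3 (0.161), 4 (0.0550) or 5 (0.0508).

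Haem genes had 2.0 distal regions per gene (adjusted p = 0.137, permutation test across genes), with 5 at Abcb10, and stem and progenitor genes 1.92 (0.137), with 9 at Lyl1. Stem genes passed the threshold against random lists matched on nearby TSSs (0.0499) and without replicate 1 (0.0306). The remaining lists ranged from 0.4 in stellate to 1.58 in cell cycle genes, and hepatoblast genes had 0.818, with 4 at Krt8. Of the genes that the naming rule took from these lists, with ties settled by alphabetical order, Cyp1a2 had 5, and Gp9, Cd79a, Slc17a7 and Mcm5 had 4 each. Of all protein-coding genes, those with most distal regions were Btn2a2 (18), Btn1a1 (17), Hist1h2bh and Hist1h3f (16 each), Abt1, Hist1h3g and Zfp184 (15 each), and Fcgr3, Hist1h2af and Hist1h4h (14 each). Of these 10 genes, 9 lie on chromosome 13, among the clustered histone genes or near them, and Fcgr3 lies on chromosome 1. Those on chromosome 13, except Zfp184, lie between 23418361 and 23545312. The 50 kb windows of such neighbours overlap, so 1 region can count for several of these genes.

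The strain label raises the question of what the globin loci look like. In the beta-globin cluster (chromosome 7, 103812524 to 103853216) the adult genes Hbb-bs (2.87 ± 0.582) and Hbb-bt (1.61 ± 0.973) had a promoter peak in all 5 libraries. The embryonic genes Hbb-y and Hbb-bh1, and Hbb-bh2, had none in any. The cluster held 26.1 ± 7.69 bp per kb listed at an FDR below 0.05, in the 87.5th ± 5.09 percentile of windows of its size on chromosome 7. In the LCR window upstream of Hbb-y (103853217 to 103883216) the values were 29.5, 0, 0, 0 and 8.0 bp per kb in replicates 1 to 5, a mean of 7.49 ± 12.8, and the median window of the chromosome held 0. Without replicate 1 the mean was 2.0.

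The annotated LCR fragment with sites 5'HS1 to 5'HS6 (103857890 to 103877545, 19.7 kb) held no peak and no listed base in replicates 2, 3 and 4. Replicate 1 had peaks at 5'HS1 (density 1.52), 5'HS4 (2.55) and 5'HS6 (1.28), and replicate 5 had 1 peak at 5'HS2 (1.06). Of the sites beyond Hbb-bt at the other end of the locus, 3'HS1 had a peak in 1 library and HS-3'beta2 in 2. Inside the cluster, HS-3'beta1 (between Hbb-bt and Hbb-bs) and HS-E1 (between Hbb-bh1 and Hbb-y) had none. The files list bases only below an FDR of 0.05, so an empty stretch is one where nothing passed that limit.

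The alpha-globin locus was open in every library. The 50 kb upstream of Hba-x (chromosome 11, 32226400 to 32276399) held 75.4 ± 31.1 bp per kb (97.8th ± 1.17 percentile), and the cluster (32276400 to 32300873) 142 ± 75.5 (98.5th ± 1.79 percentile). Of its annotated upstream sites, 6 had a peak in all 5 libraries: HS-10 (6.21 ± 2.19), HS-31 or MCS-R1 (4.85 ± 2.55), HS-26 or MCS-R2 (3.92 ± 1.72), HS-21 or MCS-R3 (2.80 ± 0.674), HS-8 or MCS-R4 (2.59 ± 0.389) and HS-38 (2.07 ± 0.813). In the annotation HS-10 is also named HS C-10, and HS-38 is also named HS C-38. With 1 tissue, these values cannot tell sites open only in red cells from sites open in other cells too. HS-29 had a peak in 4 libraries, and HS-45, HS-39, HS-15, HS-14.5 and HS-12 had none within their annotated edges. HS-39 ends at 32237103, and a peak started at 32237138 to 32237167 in replicates 1, 2, 4 and 5. HS-12 ends at 32264792, and a peak started at 32265081 to 32265217 in all 5 libraries. The theta genes Hbq1a (2.33 ± 0.741) and Hbq1b (3.65 ± 1.03) had a promoter peak in all 5 libraries, Hba-a1 in 2, and Hba-a2 and Hba-x in none. In the reference, 88% of the words of the Hba-a1 promoter and 93.2% of those of the Hba-a2 promoter occur more than once, against 0% for Hba-x and 38.1% for Hbb-bs.

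**Figure D3:**
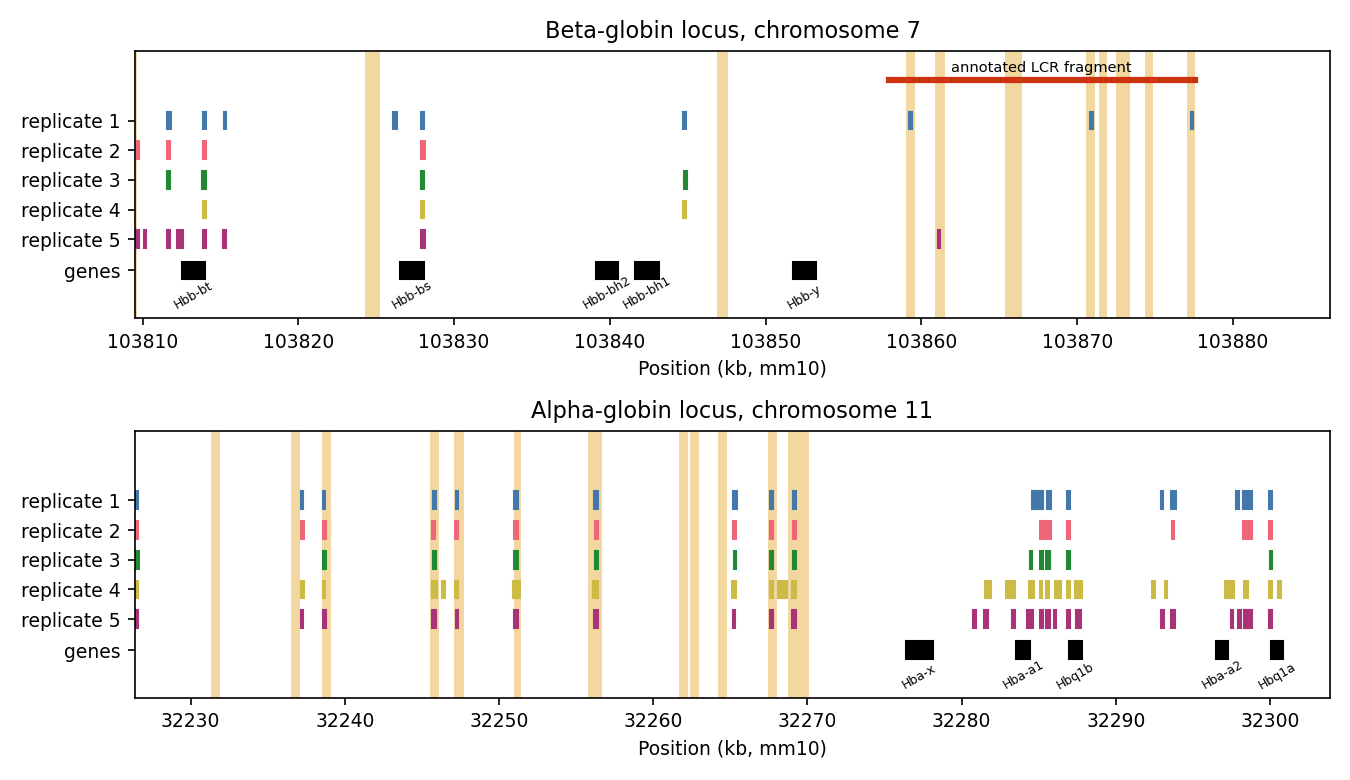
Peaks of each replicate (coloured blocks) along the beta-globin locus on chromosome 7 and the alpha-globin locus on chromosome 11, by position in kb, with genes as black boxes, annotated hypersensitive sites as tan bands and the annotated LCR fragment as a red line. The fragment holds 3 peaks in replicate 1, 1 in replicate 5 and none in the others, while 6 annotated sites upstream of the alpha-globin genes hold a peak in every replicate.

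Motifs that red cell factors bind were among those enriched near the centres of distal peaks. A motif match does not tell which factor binds there. The log2 ratio of sites near the centre of distal peaks to sites in the flanks was 3.48 ± 0.28 (SD, n = 5) for NFE2, 2.51 ± 0.59 for the paired GATA and E-box motif bound by GATA1 with TAL1, 1.11 ± 0.12 for the CACCC motif of the KLF family and 0.86 ± 0.50 for GATA alone. CTCF, the factor of chromatin loop anchors, had the highest ratio, 5.90 ± 0.42, and REST had 4.74 ± 1.34 from a mean of only 52.6 sites. The liver factor motifs FOXA (−0.40 ± 0.32) and HNF4A (−0.32 ± 0.23) lay below 0. Each of these had the same sign in all 5 libraries (exact sign-flip permutation p = 0.063, the smallest possible; adjusted p = 0.0848). CEBP, a motif of liver and myeloid factors, was above 0 in all 5 libraries, but with only 7 to 14 sites in each. RUNX (0.30 ± 0.35) and NFY (0.43 ± 0.30) were above 0 in 4 libraries, and AP1 (0.79 ± 0.29), ETS (0.86 ± 0.23), YY1 (0.58 ± 0.20) and NRF1 (2.13 ± 0.48) in all 5. Against base-shuffled sequence of the same windows ETS had only 0.013 ± 0.27, with replicates 4 and 5 below 0.

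Promoter peaks shared some of these motifs, KLF with a higher ratio to flanks than in distal peaks, and differed in others. The ratio was 3.40 ± 0.18 for CTCF, 3.19 ± 0.23 for NRF1, 2.98 ± 0.17 for ETS, 1.95 ± 0.38 for YY1, 1.94 ± 0.38 for NFE2, 1.93 ± 0.16 for NFY, 1.62 ± 0.13 for KLF and 0.52 ± 0.23 for the GATA and E-box motif. It was below 0 for GATA (−1.05 ± 0.18), RUNX (−1.03 ± 0.14) and FOXA (−0.99 ± 0.13), and −0.04 ± 0.09 for AP1. Against base-shuffled sequence of the same windows the ratios below 0 turned positive, for distal FOXA (0.79) and HNF4A (0.96) as for promoter GATA (0.43), RUNX (0.45) and FOXA (1.26). KLF was then not higher at promoters, with a mean of 1.72 there and 1.83 in distal peaks. CEBP, RFX, REST and HNF4A at promoters, MEF2, HNF1 and the OCT and SOX motif had fewer than 20 sites per library on average and give no firm ratio.

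**Figure D4:**
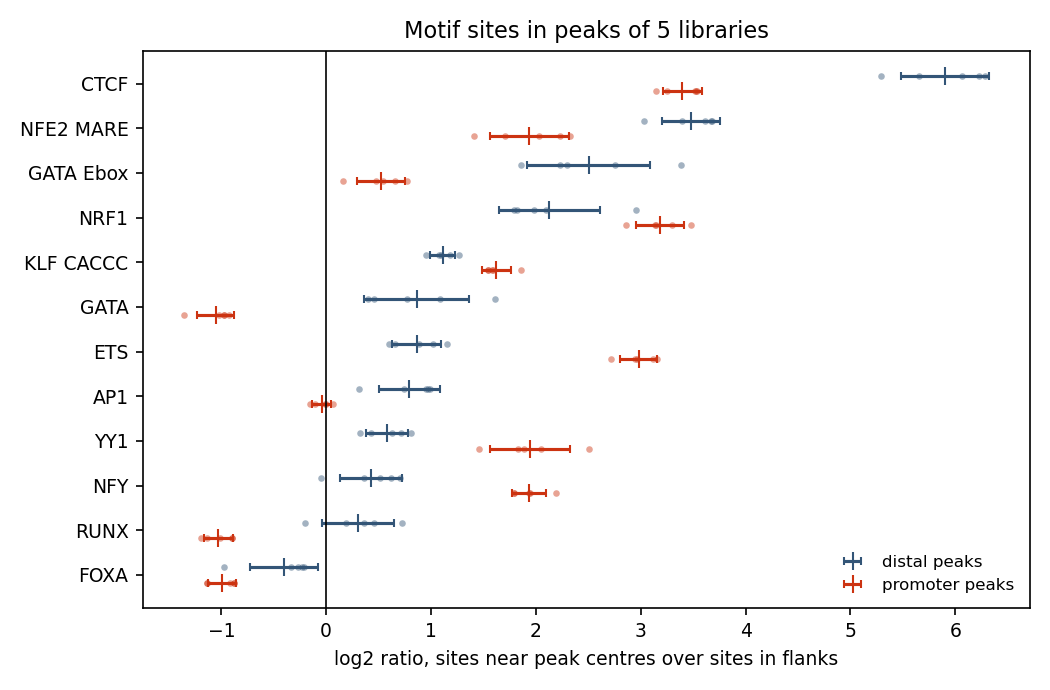
Log2 ratio of motif sites near peak centres to sites in the flanks, for 12 motifs, in distal (blue) and promoter (red) peaks; points are the 5 libraries, and bars the mean and SD. GATA lies at 0.86 in distal and at −1.05 in promoter peaks.

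Footprints lay over many of these motifs. The libraries held 131640 ± 42758 footprints (SD, n = 5) with a median length of 10 bp, of which 87.7% ± 3.00 lay inside peaks, and 73.8% ± 9.57 of peaks held at least 1. Of CTCF sites in peaks, 76.9% ± 15.5 met a footprint, against 30.3% ± 7.22 of random positions in the same peaks (log2 ratio 1.35 ± 0.10). The CTCF share was 60.1% and 60.5% in replicates 1 and 3, which had the lowest implied depth, and 82.3% to 90.8% in the others. Of NRF1 sites 94.1% met a footprint, against 44.3% of random positions (1.09 ± 0.08). The ratio was 1.39 ± 0.11 for NFE2, 0.83 ± 0.05 for KLF, 0.62 ± 0.19 for the GATA and E-box motif, 0.53 ± 0.16 for AP1, 0.50 ± 0.07 for ETS, 0.37 ± 0.23 for GATA and 0.32 ± 0.18 for YY1. Among motifs with few sites the ratio was 1.22 ± 0.20 for REST (mean 62 sites) and 0.67 ± 0.33 for MEF2 (25 sites). For CEBP, a motif of liver and myeloid factors, it was 0.90 ± 0.11 from a mean of 22.6 sites. There 49.2% met a footprint, against 25.1% of random positions. FOXA sites met footprints less often than random positions, 9.77% against 19.4% (−1.0 ± 0.24). These had the same sign in all 5 libraries (exact sign-flip permutation p = 0.063, the smallest possible; adjusted p = 0.0848). NFY (0.11 ± 0.13), RUNX (0.05 ± 0.12) and HNF4A (−0.12 ± 0.12) did not have the same sign in every library.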

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

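The tests in this part were chosen only after the result was seen, except the test of chromosome Y regions against repeats, whose expected outcome was written before. A library counted as far from the others when its gap to the nearest library, over the range of all 5, passed Dixon's 95% critical value. This held for 11 of 100 measures, 8 of them in replicate 1; chance alone picks about 1 in 20 groups, and the measures are not independent of each other.

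Replicate 1 was far from the others in the sequence it called and in what lay there. A GA repeat lay near the centre of 18.7% of its regions (others 0.116% to 0.219%), and 36.9% were mostly soft-masked (others 4.74% to 7.50%). A footprint lay in 57.2% of its peaks (others 74.5% to 80.4%). Its log2 ratio was 1.86 for KLF in promoter peaks (others 1.54 to 1.59), 2.96 for NRF1 in distal peaks (others 1.79 to 2.10) and −0.98 for FOXA in distal peaks (others −0.34 to −0.21). It listed 29.5 kb on chromosome Y (others 7.92 to 13.7) and 29.5 bp per kb in the LCR window (others 0 to 8.0). Replicate 4 had the lowest log2 ratio for GATA in promoter peaks, −1.36 (others −1.02 to −0.92). Replicate 3 had 53.8% of stem and progenitor promoters open, while the other libraries all had 69.2%. Replicate 2 had 20% of lymphoid promoters open, while the others all had 10%, a step of 1 gene of 10.

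The first pattern weighed is the 23927 regions called only in replicate 1. The tables argue against low depth, since replicate 3, with the lowest implied depth, had a GA repeat in only 0.0355% of its own regions. Reads shared between copies of one sequence remain possible for the regions with a GA repeat, 63.0% of which have a central 32-base word that occurs more than once, but are argued against as the whole cause of those without one, where the share was 31%; that share is still above the 4.64% to 11% of regions called only in another library and the 2.06% of regions found in all, so such reads stay open for part of them. With mostly soft-masked peaks left out, 11.6% of the regions of replicate 1 were its own, against 7.63% to 20.2% in the others. A difference in how reads of this library were filtered or prepared stays open and untested, and no biological explanation was tested because the design has 1 group.

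The second pattern is the 4 peaks inside the LCR fragment in replicates 1 and 5, with none in replicates 2, 3 and 4. The positions argue against random calls, within limits. All 4 peaks lie on annotated sites, which random placement in the fragment would give with a probability of 0.0110. That value takes the peaks as independent, though 3 come from replicate 1, and was computed after their positions were seen. The sequence of these peaks argues against reads shared with other mouse sequence as well, since 0% of its 32-base words occur elsewhere in the reference. Cells with an intact LCR cannot be told apart from other sources, because these files cannot show the genotype. Replicate 1 had listed bases at 5'HS1, 5'HS4 and 5'HS6 and replicate 5 at 5'HS2, with 0 sites in common. Whether the 2 libraries share a site does not decide whether either holds such cells. Reads from sequence carried by the YAC were not tested, as no other genome was used here.

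The third pattern is chromosome Y in replicate 1. Peaks in repeats remain a possible source: of 134 chromosome Y regions in replicate 1 only 14 were not mostly soft-masked, against 11 to 21 in the other libraries. Fewer female cells in the sample were not excluded: replicate 1 alone had no peak at the promoter of Xist, the RNA of the inactive X, and its mean relative density at 4 chromosome Y promoters was 0.360, against 0.339 in replicate 5, which had an Xist peak, and 0.132 to 0.181 in the others. Values on chromosome X went both ways. The ratio of median density on X to that on the autosomes was highest in replicate 1, at 0.778 (others 0.636 to 0.755). The relative density at the promoter of Eif2s3x, which escapes X inactivation, was lowest there, at 1.02 (others 1.21 to 1.73). At the promoter of Kdm5c, also on X, it was 2.65 in replicate 1, 2.29 in replicate 5 and 3.04 to 3.81 in the others. The sex of the embryos was not collected, so the mix of sexes stays open.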

How the results depend on the processing

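The alternative without mostly soft-masked peaks was chosen after seeing the data; the others were planned. Of 786 alternative values for 107 results, 739 counted as the same, 17 became weaker, 4 stronger, 10 moved and 16 reversed. For each gene list the same meant an unchanged side of the threshold, with direction checked only where the main call passed it. For other results it meant an unchanged direction, a count within 1.5-fold or a shift below the spread. The calls for erythroid, hepatoblast, adult hepatocyte, macrophage, endothelial, housekeeping and cell cycle promoters and for erythroid distal regions were kept under every alternative run for them; soft-masking was not varied for gene lists, nor top-scored peaks for distal regions. Without mostly soft-masked peaks the mean Jaccard index was 0.436 and 21619 regions were found in all libraries. What depth limits was not tested; the depth is implied by the density steps only. For the changes below the cause was not tested. No paired analysis was possible because there is 1 group.

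The shorter peak list gave 33569 peaks on average, a promoter share of 66.2% and 2 lists above for distal regions, the globin list counted among them. Equal numbers of top-scored peaks gave a Jaccard index of 0.503 and 76.2% shared peaks, and overlap of 50% of both peaks 51.6%. Regions in all libraries gave a rho of 0.897, and regions in 3 or more libraries a promoter share of 41.8%.

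Promoter differences from other genes, in percentage points, were 33.4 for haem genes and −28.5 for stellate genes with promoters of 1000 bp. With the shorter list they were −43.6 for megakaryocyte, −33.6 for lymphoid and −33.6 for muscle genes, and with regions in 3 or more libraries −35.2 for stellate and −35.2 for muscle genes. Top-scored peaks gave −35.8 for neuronal genes. Leaving out 1 replicate gave 30.9 to 34.2 for haem and −38.4 to −31.0 for stellate genes.

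Distal regions per gene above random lists were 0.602 for macrophage and 0.957 for housekeeping genes with the shorter list, 1.86 and 2.07 within 100 kb, where 2 lists stayed above, the globin list counted among them, 1.09 for macrophage genes in 3 or more libraries and 1.15 for stem genes against matched lists. The macrophage call was lost under all 3 of its settings here, and leaving out 1 replicate gave 1.20 to 1.33 for macrophage, where the call held only without replicate 2, and 0.773 to 1.55 for stem genes.

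Against base-shuffled sequence the log2 ratio in distal peaks was 0.96 for HNF4A, 0.79 for FOXA, −1.28 for CEBP and 0.70 for HNF1, and in promoter peaks 0.43 for GATA, 1.07 for AP1, 0.45 for RUNX, 0.75 for HNF4A, 1.26 for FOXA, −0.45 for CEBP, 0.32 for HNF1 and 2.47 for MEF2. Windows of 50 bp gave 0.10 for AP1 and 0.023 for MEF2 in promoters, and leaving out 1 replicate −0.13 to 0.10 for MEF2. Footprints in peaks found in all libraries gave −0.042 for RUNX and 79111 footprints on average.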

Other observations

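All values in this part were chosen after the data were seen, and none was tested against chance. The paired GATA and E-box motif, bound by GATA1 with TAL1, lay in 659 of the 9850 distal regions found in all libraries. A region with it lay within 50 kb of 11 of 24 erythroid genes (45.8%), 3 of 11 haem genes, 3 of 10 globin genes (all at the alpha-globin locus), 4 of 14 macrophage and myeloid genes, 2 of 13 stem and progenitor genes, 2 of 14 housekeeping genes, 1 of 10 lymphoid genes and 1 of 12 cell cycle genes, against 5.18% of all protein-coding genes. Lists with more distal regions have more chances to hold the motif: as a share of each list's distal regions, counted per gene, it was 17.5% for erythroid, 13.6% for haem, 12.9% for macrophage and myeloid and 6.52% for globin genes, against 5.88% over all genes. It lay near none of the 22 hepatoblast, 13 adult hepatocyte, 10 megakaryocyte, 10 endothelial, 10 stellate, 10 neuronal or 10 muscle genes. The genes with most such regions were Cbfa2t3, which encodes a partner of TAL1, Hemgn (hemogen, a red cell gene) and its neighbour Trmo, with 3 each.

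Motif ratios were also taken in distal regions found in all 5 libraries and in those called in a single library. In those found in all 5 libraries the log2 ratio was 1.61 for GATA, 3.36 for the GATA and E-box motif and 4.81 for NFE2. In those called only in replicates 1 to 5 it was −1.15, 0.14, 0.74, −0.94 and 0.0069 for GATA, and −0.68, 0.74, 2.61, −0.40 and 0.80 for the GATA and E-box motif. Among the single-library sets CTCF sites were most frequent in replicate 5, with 743 sites in 11986 distal regions (62 per 1000) and a log2 ratio of 5.78, against 18 sites in 22532 regions in replicate 1. Distal regions found in all libraries had 908 sites in 9850 regions (92.2 per 1000). Regions found in all libraries but replicate 1 included a run of 18 on chromosome 4, between 3050044 and 3085920.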
